A study of Rattus norvegicus with 10 samples.

How the data were processed

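The series holds 10 expression arrays of kidney RNA from male weanling Wistar rats fed for 6 days, each array with 1 pool of 3 animals. Groups were read from the sample labels and fixed before the data were examined: necrotic, deficient vegetable oil, control vegetable oil, deficient fish oil and control fish oil kidneys, 2 pools each. The design text names 4 conditions, and the labels divide the choline-deficient vegetable oil diet by the word necrotic. How the animals were sorted and the pools made is not stated. The sample labels call the vegetable fat corn oil, and the protocol names corn and hydrogenated oils. Spread between the 2 pools of a group measures variation between pools of animals, not between single animals, and the number of arrays limits the precision.

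The deposited values are log2 intensities per probe set, made by the authors with RMA (background correction, quantile normalization and median polish) per the submitters' processing notes. The RMA software, its version and the probe set definition are not given in the sources used here. The values run from 1.62 to 14.72, with array medians between 7.28 and 7.43, and were used as deposited without further scaling or filtering. Of 29214 probe sets, 15633 were listed in the platform annotation and 13581 were not and stayed unnamed. Of those listed, 15310 had 1 gene symbol and 323 had several; 15279 were matched by Entrez number to the current gene table, which changed 0 symbols, and 31 kept the platform symbol. This named 14506 genes, 527 of them with more than 1 probe set. The current gene table (assembly GRCr8) was used for names only, since the array files name no genome build and no positions are given. Cross-hybridisation between close paralogs (the Klk1, Ugt2b and alpha globin families) was not tested.

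All 5 groups were fitted together in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 5 residual and 3.59 prior degrees of freedom, and 9 contrasts were tested, 2 of them interactions of choline and oil. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, with a threshold of 0.05. Rose, fell, higher and lower for single genes refer to this threshold, and the adjusted p in the text are these moderated ones. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

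Genes were named by a rule: per contrast the 12 largest rises and 12 largest falls among called probe sets with 1 symbol, up to 4 members of each called list, and 9 genes fixed in advance. Where fewer than 5 probe sets passed, the 5 with the smallest p are given as values only. A few further list members with the largest values were chosen after the values were seen. The 30 gene lists were written from general knowledge, covering cell types (proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct, podocyte, endothelium, macrophage, neutrophil, lymphocyte, erythroid, adipocyte, adrenal gland) and processes. The adipocyte and adrenal gland lists hold markers of neighbouring tissue that a kidney sample could contain. The processes are tubular injury, cell cycle, cholesterol synthesis, fatty acid synthesis, PPAR alpha targets, choline metabolism, cytokines, complement, extracellular matrix, NRF2 targets, unfolded protein response, heat shock, p53 targets, immediate early genes, mitochondrial respiration, eicosanoid metabolism, renin-angiotensin genes and interferon response. At most 1 gene of any list is also in another list. Each gene was represented by its probe set with the highest mean, over 14506 genes.

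Lists were tested with camera (preset correlation 0.01), which compares a list with all other genes, with camera using an estimated correlation, and with fry, which tests whether a list's genes move one way on balance. With an estimated correlation camera also tests on the 5 residual degrees of freedom. Its p can therefore be much larger even where the estimated correlation is near 0.01. Counts adjusted over the list alone apply the adjustment to the members only. On simulated data with the spread of these arrays (5 runs, 200 changed probe sets each), 2-fold changes were recovered at 75.2% to 82.8% in the pairwise contrasts tested and at 22.4% in the interaction tested, with 4.7% to 6.7% false calls. Recovery at an adjusted threshold depends on how many probe sets change, so it may be lower in contrasts with few calls. With no list changed, 0 lists were called (the cell cycle list had adjusted p = 0.0532), and with the cell cycle list raised by 0.5 that list alone was called. Both checks used the same draw, in which genes varied independently. The measured cell cycle list had an estimated correlation of 0.664. The checks therefore do not show how often camera calls unchanged lists of correlated genes.

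Alternatives tried were median centring, quantile normalization again, cyclic loess, filters at the 25th and 50th percentile of the mean, a trend and robust prior, only the groups of a contrast, array weights, the replicate number as a block, and leaving out each array. A fit of probe sets with 1 symbol only was added after the data were seen. Other background corrections and blocks for slide or scan date could not be run, since the deposited values are already summarised and no such dates are given.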

Results

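Kidney RNA from male weanling Wistar rats was measured on 10 expression arrays after 6 days on a diet that lacked or contained choline, the nutrient from which phosphatidylcholine and betaine are made. The fat was either vegetable oil (corn and hydrogenated oils) or menhaden fish oil. Each array held RNA of 1 pool of 3 animals, and every group had 2 pools. The labels divide the kidneys of the choline-deficient vegetable oil diet into pools called necrotic and pools without that word, which gives 5 groups of 2 arrays. They are named here the necrotic, deficient vegetable oil, control vegetable oil, deficient fish oil and control fish oil kidneys, where control means choline-supplemented. The protocol names 4 diets, so the word necrotic names no diet, and how those animals were sorted into pools is not stated. Every array gave 29214 log2 values, with medians between 7.28 and 7.43, and the small number of arrays limits the precision of every difference. Errors are moderated standard errors of the log2 difference, with 2 pools per group. Their spread was estimated per probe set over all 5 groups, so it is not that of the compared pools alone.

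On the first principal component, which held 54.2% of the variance, the necrotic arrays lay at -71.4 and -73.3 and the 6 control and fish oil arrays between 20.8 and 35.5. The deficient vegetable oil arrays lay between them, replicate 1 at 6.6 and replicate 2 at -20.2. On the second component, with 11.7% of the variance, the control vegetable oil arrays lay at -26.6 and -30.6 and the 4 fish oil arrays between 4.1 and 23.4. The necrotic arrays lay at 15.8 and -15.7 and the deficient vegetable oil arrays at -8.3 and 12.7 there, so this component did not separate the oils. Replicate 2 of the deficient vegetable oil kidneys correlated with necrotic replicate 1 at r = 0.9842 across all probe sets, against 0.9737 for replicate 1, and probe sets are not independent replicates. Between the 2 arrays of a group, the probe sets that differed 2-fold or more numbered 391 in the necrotic, 488 in the deficient vegetable oil and 473 in the control fish oil kidneys. They numbered 166 in the control vegetable oil and 271 in the deficient fish oil kidneys.

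**Figure D1:**
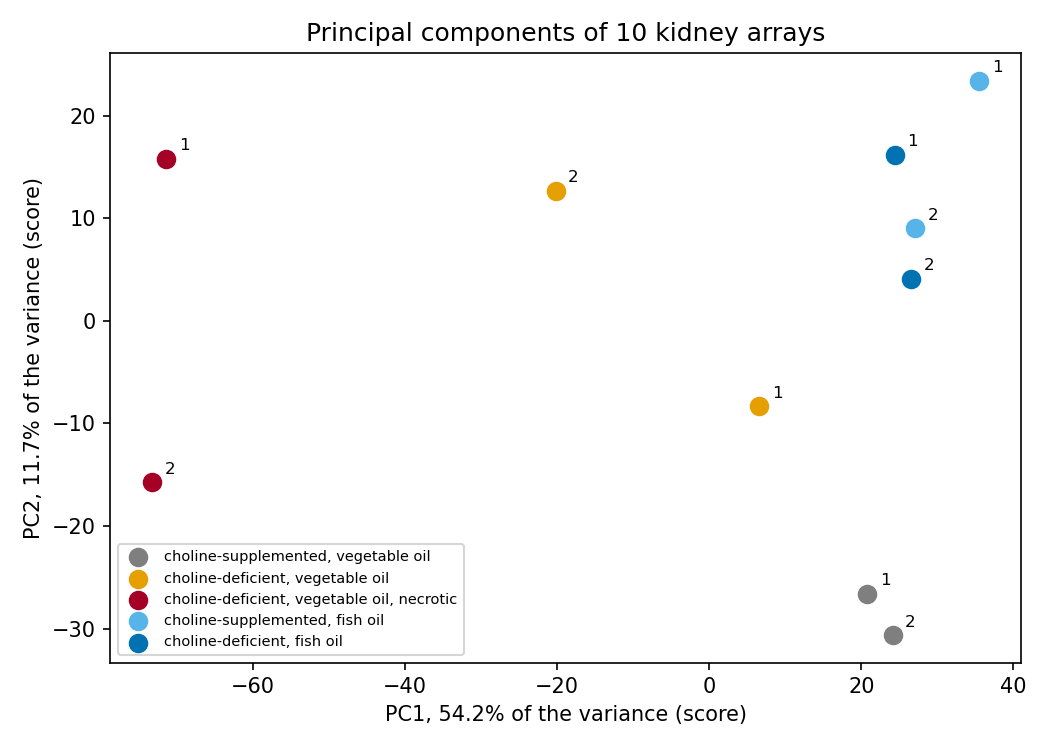
Scores of the 10 kidney arrays on the first and second principal components of the log2 values, 1 point per array (pool of 3 animals), coloured by group and numbered by replicate. The necrotic arrays lie at -71.4 and -73.3 on the first component and the deficient vegetable oil arrays at 6.6 and -20.2, with the other arrays at 20.8 or above.

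The series addresses kidney failure brought on by lack of choline, and the first comparison set the necrotic kidneys against kidneys given the same oil with choline. Markers of tubular injury were higher and transporters of the tubule lower. Havcr1, a membrane protein that injured proximal tubule cells display, rose by 6.77 ± 0.60 (adjusted p = 0.000191), from 6.67 and 6.56 on the control arrays to 13.24 and 13.53. Lcn2, an iron-siderophore binding protein released by injured tubules, rose by 3.60 ± 0.31 (adjusted p = 0.000161). Slc34a1, the sodium-phosphate cotransporter of the proximal brush border, fell by 3.51 ± 0.11 (adjusted p = 3.04e-06), from 14.00 and 14.03 to 10.58 and 10.43. Egf, the growth factor made by the distal nephron, fell by 4.93 ± 0.17. The probe sets are 10733017 for Havcr1, 10844331 for Lcn2, 10797258 for Slc34a1 and 10826725 for Egf. Of the 29214 probe sets 6098 passed at an adjusted p under 0.05, 2985 higher and 3113 lower, with 824 rises and 1100 falls of at least 2-fold. After median centring of each array 1974 were higher and 3781 lower, since it moved the median of all probe sets from 0.063 to -0.038. Without control replicate 1 the count was 3213 and without control replicate 2 it was 3003.

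Further large rises in the necrotic kidneys were those of single genes of several kinds. Fgg and Fgb, chains of fibrinogen, rose by 4.95 ± 0.36 and 4.02 ± 0.34, Serpina3n, an acute phase protease inhibitor, by 4.89 ± 0.68, and A2m, alpha-2-macroglobulin, by 4.08 ± 0.26. Lbp, which binds bacterial lipopolysaccharide, rose by 3.73 ± 0.42. Hmox1, which degrades heme, rose by 4.69 ± 0.47, Slc7a11, the cystine carrier, by 3.87 ± 0.40, and Olr1, a receptor for oxidised lipoprotein, by 4.08 ± 0.23. Cxcl2, a neutrophil chemokine, rose by 4.22 ± 0.25, Gpnmb, a glycoprotein of macrophages, by 4.38 ± 0.22, and Trh, the thyrotropin-releasing hormone, by 3.75 ± 0.49. Of the 23 measured tubular injury genes 20 rose and none fell (median log2 difference 1.73, camera adjusted p = 4.34e-12, fry adjusted p = 0.000183; adjusted p = 0.119 with an estimated correlation). Among them were Krt18, an epithelial keratin, at 2.02 ± 0.14, Tnfrsf12a, the TWEAK receptor, at 2.22 ± 0.16, Clu, a secreted chaperone, at 2.61 ± 0.30, and Spp1, osteopontin, at 1.65 ± 0.20.

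Inflammation, matrix and cell death lists also rose. Of 39 genes of cytokines, chemokines and NF-kB targets 24 rose (median 0.97), with Ccl3, a macrophage chemokine, at 3.07 ± 0.13, Socs3, the feedback inhibitor of cytokine signalling, at 3.16 ± 0.17, and Nfkbiz at 2.17 ± 0.13. Of 31 complement, coagulation and acute phase genes 21 rose and 1 fell (median 0.81), with Fga at 3.23 ± 0.17 and Procr, the protein C receptor, at 1.64 ± 0.14. Camera gave adjusted p = 6.36e-09 and 3.98e-08 for these lists, and each had adjusted p = 0.0988 with an estimated correlation. Of 36 extracellular matrix genes 27 rose and 1 fell (median 1.14, adjusted p = 3.13e-13; 0.129 as adjusted p with an estimated correlation), with Lox, which crosslinks collagen, at 2.5 ± 0.17 and Tgfb3 at 2.00 ± 0.15. Of 35 p53 target and cell death genes 22 rose and 1 fell (median 0.64, adjusted p = 9.58e-06; adjusted p = 0.0988 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, was at 1.52 ± 0.25, and Ripk3, the kinase of necroptosis, at 1.5 ± 0.24. Of 29 immediate early genes 18 rose and 1 fell (median 0.80, adjusted p = 5.29e-08; adjusted p = 0.184 with an estimated correlation), with Myc at 2.05 ± 0.17 and Klf6 at 1.55 ± 0.12. Of 49 cell cycle genes 11 rose (median 0.59, camera adjusted p = 0.00035, fry adjusted p = 0.17; adjusted p = 0.604 with an estimated correlation), among them the replication helicase subunits Mcm7 at 0.78 ± 0.17 and Mcm5 at 0.94 ± 0.23. The cell cycle call ended without necrotic replicate 2.

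Every tubule segment list was lower in the necrotic kidneys. Of 42 proximal tubule genes 37 fell and none rose (median -1.59, camera adjusted p = 1.83e-23, fry adjusted p = 0.000112; adjusted p = 0.119 with an estimated correlation). Miox, which opens the ring of myo-inositol, was at -4.23 ± 0.15, Slc5a2, the sodium-glucose cotransporter, at -2.56 ± 0.12, and Slc9a3, the sodium-proton exchanger, at -2.63 ± 0.12. Of 11 thick ascending limb genes 7 fell (median -0.80, adjusted p = 8.36e-05; adjusted p = 0.184 with an estimated correlation), with Umod, uromodulin, at -3.29 ± 0.13 and the potassium channel Kcnj1 at -1.48 ± 0.12. Of 13 distal convoluted and connecting tubule genes 8 fell (median -1.29), with Klk1, tissue kallikrein, at -4.92 ± 0.19, Calb1, a calcium buffer, at -4.98 ± 0.31, and Slc12a3, the thiazide-sensitive cotransporter, at -3.27 ± 0.15. Of 23 collecting duct genes 17 fell and 1 rose (median -1.03), with the ammonia transporters Rhcg at -2.13 ± 0.11 and Rhbg at -1.69 ± 0.12 and the vasopressin receptor Avpr2 at -1.51 ± 0.15. Camera gave adjusted p = 9.01e-08 and 1.01e-09 for these distal lists, and each had adjusted p = 0.0988 with an estimated correlation. The largest falls outside these lists were those of Cacng5 (-4.84 ± 0.44), Acmsd, an enzyme of tryptophan breakdown (-4.74 ± 0.25), Rgn, regucalcin (-4.65 ± 0.39), Acsm3 (-4.65 ± 0.14), Folh1 (-4.64 ± 0.26), the nuclease Dnase1 (-4.43 ± 0.15), Hnmt, which methylates histamine (-4.43 ± 0.29), and Spp2 (-4.35 ± 0.26). Alb, albumin, had -4.89 ± 1.19, and its call ended without any 1 of the 4 arrays compared.

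Metabolic lists were lower in the same kidneys. Of 48 genes of mitochondrial respiration and the citrate cycle 37 fell (median -0.66, adjusted p = 5.35e-16; adjusted p = 0.204 with an estimated correlation), with Sdha of succinate dehydrogenase at -1.04 ± 0.12 and Mdh1, a malate dehydrogenase, at -1.26 ± 0.16. Of 43 PPAR alpha target and fatty acid oxidation genes 23 fell and 4 rose (median -0.57, adjusted p = 8.51e-07; adjusted p = 0.262 with an estimated correlation). Ehhadh, of peroxisomal oxidation, was at -2.06 ± 0.19, Acsl1, which activates fatty acids, at -1.68 ± 0.14, and Acadm, the medium-chain dehydrogenase, at -1.43 ± 0.15, while Pdk4, which inhibits pyruvate dehydrogenase, rose by 0.87 ± 0.18. Of 41 choline, betaine and one-carbon genes 19 fell and 4 rose (median -0.37, adjusted p = 0.000169; adjusted p = 0.204 with an estimated correlation). Slc22a2, an organic cation transporter, was at -2.29 ± 0.17, Dmgdh, dimethylglycine dehydrogenase, at -2.04 ± 0.16, Bhmt2, a homocysteine methyltransferase that uses S-methylmethionine, at -2.32 ± 0.19, and Cbs, of transsulfuration, at -2.32 ± 0.20. Of 19 fatty acid synthesis genes 13 fell (median -0.78), with Acss2 at -2.16 ± 0.19 and the desaturase Scd at -2.08 ± 0.26, and of 20 cholesterol synthesis genes 5 fell (median -0.45), with Fdft1, squalene synthase, at -1.36 ± 0.21. Of 18 heat shock genes 8 fell and 1 rose (median -0.33), with Chordc1 at -1.51 ± 0.17. For these 3 lists camera gave adjusted p = 9.25e-06, 0.00255 and 0.0036, against adjusted p = 0.204, 0.569 and 0.217 with an estimated correlation.

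Markers of other cells moved beside these groups. Of 25 monocyte and macrophage genes 18 rose (median 1.41, adjusted p = 1.80e-10; adjusted p = 0.204 with an estimated correlation), with Mrc1, the mannose receptor, at 3.33 ± 0.22, Cd163, the haptoglobin-hemoglobin receptor, at 2.83 ± 0.21, and Cd14 at 2.23 ± 0.15. Of 15 neutrophil genes 7 rose (median 0.70, adjusted p = 0.000362; adjusted p = 0.313 with an estimated correlation), with Il1r2, the decoy receptor of interleukin 1, at 3.02 ± 0.25 and Csf3r at 1.40 ± 0.11. Of 19 endothelium genes 5 fell (median -0.22, adjusted p = 0.046; adjusted p = 0.572 with an estimated correlation), with the VEGF receptor Kdr at -1.04 ± 0.14 and Emcn at -0.73 ± 0.11. The endothelium call ended without necrotic replicate 1 or without control replicate 2. Of 12 erythroid genes 1 rose, Hemgn at 1.05 ± 0.16 (median 0.38, adjusted p = 0.0101; adjusted p = 0.262 with an estimated correlation). The podocyte (median -0.24, 2 rose and 3 fell of 14), adipocyte (-0.31, 2 fell of 10) and adrenal gland lists (0.21, 1 fell of 13) did not pass, nor did the lymphocyte list, whose median was 0.06 and mean -0.07. The NRF2 target, unfolded protein, eicosanoid, renin-angiotensin and interferon lists had medians of 0.11, 0.08, -0.08, 0.12 and 0.04 and did not pass either, and the interferon mean was -0.02. Their genes moved both ways. In that order 11 rose and 9 fell of 35, 8 and 6 of 33, 7 and 11 of 35, 6 and 6 of 26, and 6 and 1 of 40. Over all probe sets 20.87% passed. Adjusted over the list alone, 20 tubular injury, 39 proximal tubule, 18 macrophage, 29 matrix, 44 mitochondrial, 15 cell cycle and 11 cholesterol synthesis genes passed in the direction of their list.

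The next comparison set the deficient vegetable oil kidneys, which the labels do not call necrotic, against the control vegetable oil kidneys. Injury, cytokine and coagulation genes were higher, and the 4 tubule segment lists had medians between -0.45 and -0.14. Havcr1 rose by 5.85 ± 0.60 (adjusted p = 0.0051), to 11.82 and 13.11, Lcn2 by 2.5 ± 0.31, Clu by 1.79 ± 0.30 and Spp1 by 1.43 ± 0.20. Slc34a1 differed by -0.25 ± 0.11 and Umod by -0.18 ± 0.13, with adjusted p = 0.334 and 0.538. Of the 29214 probe sets 330 passed, 261 higher and 69 lower, with 164 rises and 29 falls of at least 2-fold, and 4435 had an unadjusted p under 0.05 against 1461 by chance. The count was 82 when only these groups were fitted, 40 without control replicate 1, 32 without control replicate 2, 146 without deficient replicate 2 and 714 without deficient replicate 1. Havcr1 was among the 15 of the 24 largest changes that ended without either control array, as were Csrp3, Tgm1 and all 12 falls.

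Among the largest rises in the deficient vegetable oil kidneys were those of kininogen and fibrinogen genes. Kng2 and Kng1, precursors of bradykinin, rose by 4.06 ± 0.23 and 3.28 ± 0.24, and Fgg, Fgb and Fga by 3.86 ± 0.36, 3.60 ± 0.34 and 3.52 ± 0.17. Olr1 rose by 4.04 ± 0.23, Atf3, a stress-induced transcription factor, by 3.96 ± 0.24, Igfbp1, a binding protein of insulin-like growth factors, by 3.06 ± 0.20, and Socs3 by 2.75 ± 0.17. Csrp3, a muscle LIM protein, rose by 3.26 ± 0.57 with unequal levels of 10.48 and 8.29, and Tgm1, a transglutaminase, by 2.73 ± 0.40. The falls were smaller. Sfrp2, a secreted Wnt inhibitor, was at -1.56 ± 0.26, Oxgr1, a receptor for oxoglutarate, at -1.41 ± 0.22, Casr, the calcium-sensing receptor, at -1.40 ± 0.18, and Ptgs2, the inducible cyclooxygenase, at -1.33 ± 0.19. Dnajc6, Lipg, Rdh16, Mfap4, Inpp5j, Masp1, Capn6 and Ralyl fell by between -1.32 and -1.15. Both groups share the control arrays with the necrotic comparison, and 230 of the 261 higher and 63 of the 69 lower probe sets also passed there in the same direction, against 26.7 and 7.4 for independent lists. Independent lists do not allow for the shared controls. Noise in the shared controls alone gave a covariance of 0.0187 between the differences in simulated data, against 0.123 observed. The correlation was 0.501 in the same simulated data, against 0.643 observed across probe sets, which are not independent replicates.

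By list, 10 of the 23 tubular injury genes rose (17 adjusted over the list alone, median 0.93), with Tnfrsf12a at 2.24 ± 0.16, Il24 at 2.40 ± 0.27 and Hbegf, an epidermal growth factor ligand, at 1.92 ± 0.22. Of the immediate early genes 10 of 29 rose (20 adjusted over the list alone, median 0.76), with Myc at 2.27 ± 0.17 and Klf6 at 1.63 ± 0.12. Each list had adjusted p = 0.0726 with an estimated correlation, against 8.65e-18 and 1.26e-17, and each had fry adjusted p = 0.00202. Of the cytokine list 15 of 39 rose (29 adjusted over the list alone, median 0.85, adjusted p = 2.83e-22), with Icam1, a leukocyte adhesion molecule, at 1.53 ± 0.16 and Lif at 2.16 ± 0.23, and this call held with an estimated correlation (adjusted p = 0.0485). Of the complement and coagulation list 8 of 31 rose (median 0.52, adjusted p = 1.02e-09), with Plaur, the urokinase receptor, at 1.69 ± 0.17, and of the p53 and cell death list 3 of 35 (median 0.34, adjusted p = 1.40e-07), with Bcl2a1 at 1.34 ± 0.16. Each of the latter lists had adjusted p = 0.0564 with an estimated correlation. Of 36 matrix genes 5 rose (median 0.11), with Thbs1, thrombospondin, at 1.19 ± 0.11, and of 35 NRF2 targets and metallothioneins 5 rose (median 0.05), with Mt1 at 1.14 ± 0.12 and Hmox1 at 2.66 ± 0.47. Camera gave them adjusted p = 0.000249 and 0.0091, and adjusted p = 0.397 with an estimated correlation for each. The unfolded protein list had a median of -0.03, a mean of 0.31 and 7 of 33 genes that rose, Atf3 among them, and did not pass (adjusted p = 0.059).

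The macrophage list had a median of 0.78 in these kidneys (adjusted p = 1.73e-15; adjusted p = 0.259 with an estimated correlation), with 4 of 25 genes that rose and 19 adjusted over the list alone. Gpnmb was at 2.09 ± 0.22, Cd14 at 1.55 ± 0.15 and Lyz2, lysozyme, at 1.08 ± 0.20. The neutrophil and lymphocyte lists had medians of 0.44 and 0.19 with no gene that passed (adjusted p = 0.00231 and 0.0142; adjusted p = 0.397 for each with an estimated correlation). The proximal tubule (median -0.26), thick limb (-0.34), distal tubule (-0.45) and collecting duct lists (-0.14) were lower by camera (adjusted p = 7.20e-06, 0.00231, 0.00175 and 0.00231). With an estimated correlation they had adjusted p = 0.397, 0.397, 0.334 and 0.397, and fry gave adjusted p = 0.129, 0.0525, 0.0452 and 0.105. Among their genes 2 passed, Slc9a3 at -0.83 ± 0.12 and Klk1 at -1.13 ± 0.19. The endothelium (-0.22), cell cycle (-0.57), mitochondrial (-0.18) and fatty acid synthesis lists (-0.21) were also lower by camera with no gene that passed (adjusted p = 0.0014, 1.22e-08, 2.10e-06 and 0.0122), and each had adjusted p = 0.397 with an estimated correlation. The endothelium and NRF2 calls ended without deficient replicate 1, and the lymphocyte, mitochondrial and fatty acid synthesis calls without deficient replicate 2. The adrenal, erythroid and adipocyte lists had medians of 0.16, -0.01 and -0.08 and did not pass.

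**Figure D2:**
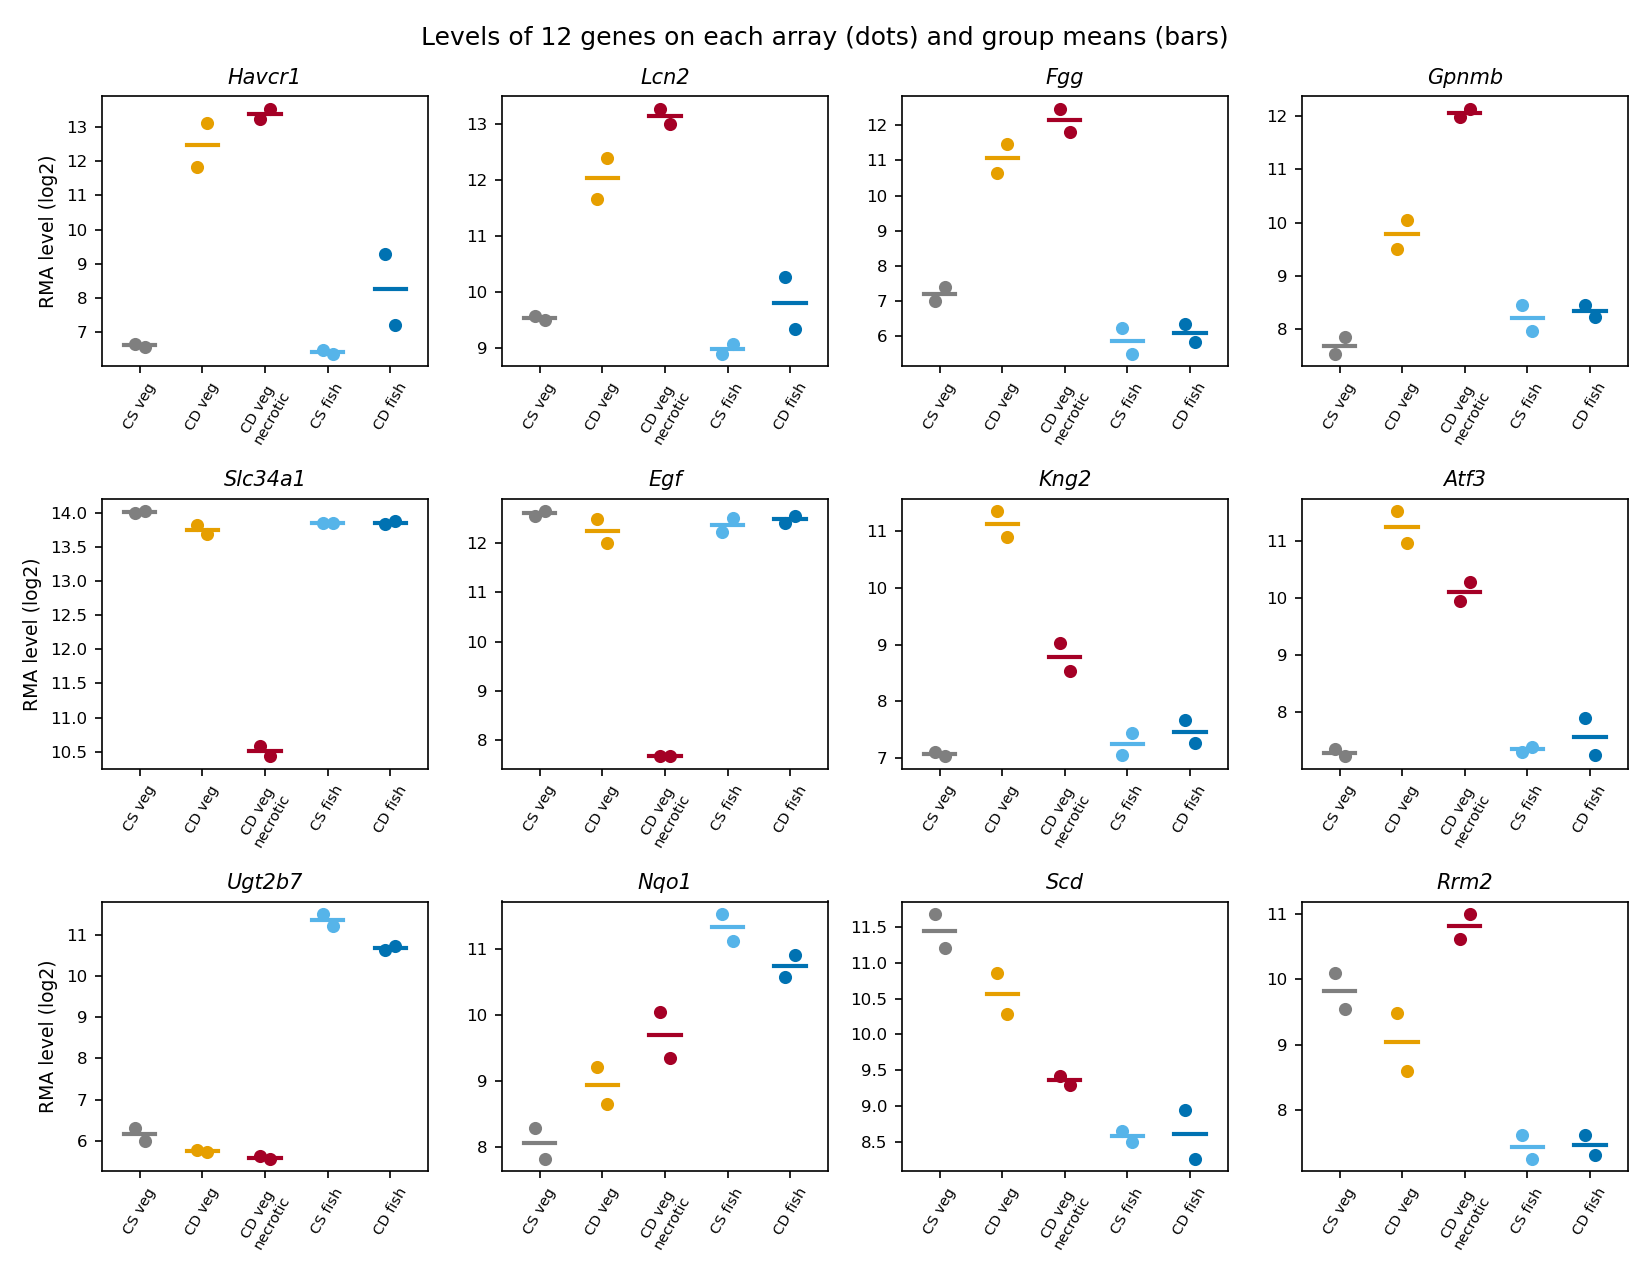
RMA levels (log2, vertical axis) of 12 genes on each array (dots) by group, with bars at the group means; CS and CD mark diets with and without choline, veg and fish the oil. Havcr1 lies at 11.82 and 13.11 in the deficient vegetable oil kidneys and at 9.30 and 7.22 in the deficient fish oil kidneys, against 6.67 and 6.56 in the control vegetable oil kidneys.

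Necrotic and deficient vegetable oil kidneys came from the same diet, and their comparison addresses what goes with the necrotic label. Brush border and distal tubule genes such as Slc34a1 and Egf were lower and the macrophage gene Mrc1 higher in the necrotic kidneys, while Havcr1 differed by 0.92 ± 0.60 (adjusted p = 0.43). Slc34a1 was at -3.26 ± 0.11, Umod at -3.11 ± 0.13 and Egf at -4.57 ± 0.17. A2m rose by 3.49 ± 0.26, Cxcl2 by 3.17 ± 0.25, Mrc1 by 3.00 ± 0.22 and Nos2, the inducible nitric oxide synthase, by 2.81 ± 0.30. In all 2860 probe sets passed, 1376 higher and 1484 lower, with 400 rises and 611 falls of at least 2-fold. The count was 654 when only these groups were fitted, 1798 without necrotic replicate 1, 1312 without necrotic replicate 2, 1040 without deficient replicate 1 and 3125 without deficient replicate 2.

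Other large rises with the necrotic label were those of C3, the central complement component (2.79 ± 0.40), Niban1 (2.65 ± 0.20), Cd163 (2.62 ± 0.21), Clmp (2.34 ± 0.21), Il1r2 (2.34 ± 0.25) and Gpnmb (2.28 ± 0.22). Serpina3n (2.88 ± 0.68) lost its call without any 1 of the 4 arrays, Trh (2.23 ± 0.49) without either necrotic array, and Ucp1, the uncoupling protein of brown fat (-3.92 ± 0.75), without deficient replicate 1 or necrotic replicate 2. Whether Ucp1 came from fat taken with the kidney was not tested. Large falls were those of Slc7a12 (-4.31 ± 0.29), Calb1 (-4.28 ± 0.31), Cacng5 (-4.27 ± 0.44), Slco1a6 (-4.15 ± 0.31), Acmsd (-4.14 ± 0.25), Dnase1 (-4.13 ± 0.15), Folh1 (-4.10 ± 0.26), Hnmt (-4.06 ± 0.29), Spp2 (-3.96 ± 0.26) and Miox (-3.87 ± 0.15). Of the proximal tubule list 39 of 42 genes fell (median -1.34, adjusted p = 4.72e-29), of the distal tubule list 6 of 13 (-0.55, 2.90e-08) and of the collecting duct list 14 of 23 (-0.90, 3.37e-10). Each had adjusted p = 0.188 with an estimated correlation. In the thick limb list 5 of 11 fell and 1 rose (median -0.46, adjusted p = 0.000669; adjusted p = 0.295 with an estimated correlation).

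Cell cycle genes were higher with the necrotic label, 26 of 49 (38 adjusted over the list alone, median 1.03, adjusted p = 3.19e-15; adjusted p = 0.302 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 was at 1.77 ± 0.31, the mitotic kinases Plk1 and Aurkb at 1.70 ± 0.29 and 1.38 ± 0.23, and Foxm1 at 1.03 ± 0.17. Of 36 matrix genes 21 rose and 1 fell (median 0.72, adjusted p = 1.11e-11; adjusted p = 0.295 with an estimated correlation), with the collagens Col1a1 at 2.19 ± 0.20 and Col1a2 at 1.95 ± 0.20 and Lox at 2.04 ± 0.17. Of 23 injury genes 6 rose (median 0.64, adjusted p = 7.22e-05; adjusted p = 0.302 with an estimated correlation), among them Krt19 at 1.01 ± 0.15 and the intermediate filament Vim at 0.85 ± 0.13. In the macrophage list 8 of 25 rose and 2 fell (median 0.45, adjusted p = 7.22e-05; adjusted p = 0.413 with an estimated correlation), with Cd68 at 1.40 ± 0.20, and in the neutrophil list 6 of 15 rose (0.54, adjusted p = 0.00104; adjusted p = 0.374 with an estimated correlation). The erythroid list had a median of 0.38 with 3 of 12 genes that rose, Hemgn, Ahsp (1.52 ± 0.26) and Alas2 (adjusted p = 0.000593; adjusted p = 0.295 with an estimated correlation). The lymphocyte list was lower (-0.23, adjusted p = 0.0426; adjusted p = 0.373 with an estimated correlation), with the cytotoxic granule gene Nkg7 at -1.28 ± 0.17, a call that ended without deficient replicate 2 or necrotic replicate 1. Mitochondrial (25 of 48 fell, median -0.50), PPAR alpha (19 of 43 fell and 1 rose, -0.41), choline (14 of 41 fell and 2 rose, -0.35) and fatty acid synthesis lists (6 of 19, -0.50) were lower (adjusted p = 2.43e-14, 1.24e-07, 0.000163 and 3.52e-05). With an estimated correlation they had adjusted p = 0.302, 0.302, 0.295 and 0.295. Cholesterol synthesis and heat shock were lower as well (median -0.36 and -0.24, adjusted p = 0.00165 and 0.011; adjusted p = 0.506 and 0.302 with an estimated correlation), and both calls ended without deficient replicate 1. The heat shock call also ended without necrotic replicate 1. The complement list was higher (median 0.17, 9 of 31 rose, adjusted p = 0.00345; adjusted p = 0.295 with an estimated correlation), and the cytokine (-0.02, mean 0.14), immediate early (-0.03) and p53 lists (0.23) did not pass. In the cytokine list 7 of 39 genes rose and 2 fell.

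With fish oil, the lack of choline was compared in the same way, as the series addresses protection by this oil. No probe set passed in limma between deficient and control fish oil kidneys, and 1036 had an unadjusted p under 0.05 against 1461 by chance. Havcr1 differed by 1.83 ± 0.60 (adjusted p = 1.0), with 9.30 and 7.22 on the deficient arrays and 6.49 and 6.37 on the controls. Lcn2 differed by 0.82 ± 0.31, Spp1 by 0.33 ± 0.20, Clu by 0.07 ± 0.30, Slc34a1 by 0.00 ± 0.11 and Umod by 0.08 ± 0.13. The named genes with the smallest p were the homeobox gene Meox2 (-0.81 ± 0.12), neuropeptide Y, Npy (-1.02 ± 0.16), the secreted phospholipase Pla2g2a (-0.96 ± 0.18), Cd226 (-0.71 ± 0.13) and Ugt2b7 (-0.70 ± 0.15), all with adjusted p = 1.0. Without deficient fish oil replicate 1, 2 probe sets passed, and Clu stood at -0.11; without control replicate 1 Clu stood at -0.04 and Umod at -0.05. On simulated data with 200 changed probe sets this contrast recovered 78.4% of 2-fold and 99.6% of 4-fold changes, and 5.2% of 1.41-fold changes. So many changed probe sets ease the adjusted threshold. The percentages therefore do not hold for a contrast in which none passed, and 2-fold changes such as that of Npy are not excluded.

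Among the lists, 13 passed camera in the fish oil comparison with medians between -0.17 and 0.16, none with an estimated correlation and none by fry, and no member passed over all genes. Fry gave tubular injury adjusted p = 0.762 here, against 0.000183 for necrotic and 0.00202 for deficient vegetable oil kidneys compared with control. Tubular injury had a median of 0.14 (adjusted p = 0.00489; adjusted p = 0.589 with an estimated correlation), with 0.32 ± 0.15 for Cd24. Its direction turned without deficient replicate 1 (adjusted p = 0.974), as did that of the immediate early list (0.974), and that of the erythroid list turned without control replicate 2 (0.688). Thick ascending limb (0.16), collecting duct (0.07), endothelium (0.16), complement (0.09) and renin-angiotensin lists (0.12) were higher by camera (adjusted p = 0.00702, 0.0258, 0.00236, 0.0448 and 0.0359), each with adjusted p = 0.589 with an estimated correlation. Podocyte (0.11), matrix (0.09) and immediate early lists (0.11) were higher too (adjusted p = 0.0359, 0.0359 and 0.0258; adjusted p = 0.726, 0.819 and 0.726 with an estimated correlation). Erythroid (-0.14), adrenal gland (-0.17), NRF2 (-0.09) and unfolded protein lists (-0.08) were lower (adjusted p = 0.00489, 0.00196, 0.00236 and 0.0258; adjusted p = 0.589 for each with an estimated correlation). Ahsp, which stabilises alpha globin, had -1.16 ± 0.26, and Cyp11b1, of corticosteroid synthesis and a marker of neighbouring adrenal tissue, -0.61 ± 0.26. Of the 13 calls 8 were kept without deficient replicate 1, 4 without deficient replicate 2, 2 without control replicate 1 and 8 without control replicate 2. The macrophage list had a median of 0.04, a mean of 0.01 and the camera direction down (adjusted p = 0.931).

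Whether the effect of lacking choline differed between the oils was tested directly as an interaction. The deficient vegetable oil pools were divided by label and the fish oil pools were not. Oil and sorting therefore cannot be told apart in either interaction. Against the necrotic kidneys, 2548 probe sets passed, 1117 with a higher and 1431 with a lower choline effect under vegetable oil. After median centring the numbers were 753 and 1679. The interaction of Havcr1 was 4.94 ± 0.85 (adjusted p = 0.0108), that of Lcn2 2.78 ± 0.44, of Clu 2.54 ± 0.42, of Slc34a1 -3.51 ± 0.16 and of Umod -3.36 ± 0.18. Of the proximal tubule list 33 of 42 genes passed lower (median -1.63, adjusted p = 5.71e-25) and of the injury list 19 of 23 higher (1.58, 6.01e-12), each with adjusted p = 0.106 with an estimated correlation. The macrophage list had 16 of 25 genes higher (median 1.35, adjusted p = 1.84e-11; adjusted p = 0.193 with an estimated correlation), with Cd163 at 3.00 ± 0.30. The count was 1022 and 955 without control vegetable oil replicate 1 or 2, 1246 and 1147 without deficient fish oil replicate 1 or 2, and 1472 without control fish oil replicate 2.

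Against the deficient vegetable oil kidneys without the necrotic label, the interaction passed for 30 probe sets, 28 higher and 2 lower, with 2892 at an unadjusted p under 0.05 against 1461 by chance. Kng2 (3.85 ± 0.33), Olr1 (3.82 ± 0.32), Atf3 (3.74 ± 0.35), Igfbp1 (2.96 ± 0.28), Kng1 (2.95 ± 0.34) and Fga (2.95 ± 0.25) led the higher ones. Socs3 (2.51 ± 0.23), Myc (2.24 ± 0.24), Angptl4, a lipoprotein lipase inhibitor (2.18 ± 0.28), Tnfrsf12a (2.16 ± 0.22), the activin subunit Inhba (2.13 ± 0.27) and Mthfd2, of mitochondrial folate metabolism (2.07 ± 0.27), followed. The lower ones were Prima1 (-1.69 ± 0.21) and the odorant receptor Or13a19b (-1.29 ± 0.17). Havcr1 had 4.02 ± 0.85 and did not pass (adjusted p = 0.184). The cytokine list had 2 of 39 genes higher (19 adjusted over the list alone, median 0.85, adjusted p = 5.56e-20; adjusted p = 0.062 with an estimated correlation), with Nfkbiz at 1.5 ± 0.18. Tubular injury (1 of 23 genes higher, 12 adjusted over the list alone, median 0.88), immediate early (2 of 29, 17, 0.83) and macrophage genes (none of 25, 12, 0.73) were higher by camera as well (adjusted p = 6.40e-14, 5.84e-14 and 3.82e-14; adjusted p = 0.115, 0.115 and 0.194 with an estimated correlation). Thick ascending limb (-0.48), distal tubule (-0.50), collecting duct (-0.26), endothelium (-0.36) and cell cycle lists (-0.56) were lower by camera with no gene that passed (adjusted p = 9.11e-05, 0.000127, 0.000116, 1.24e-05 and 5.53e-06; adjusted p = 0.194, 0.194, 0.214, 0.286 and 0.527 with an estimated correlation). The proximal tubule list was lower too (-0.26, adjusted p = 0.000131; adjusted p = 0.503 with an estimated correlation), a call that ended without deficient vegetable oil replicate 2. The count was 14 when only these groups were fitted. No probe set passed in limma without either control vegetable oil array or either control fish oil array, 7 passed without deficient fish oil replicate 2 and 90 without deficient vegetable oil replicate 1. On simulated data with 200 changed probe sets this interaction recovered 22.4% of 2-fold and 88.8% of 4-fold changes, and recovery may be lower with the 30 that passed here.

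The effect of the oil alone was measured in control kidneys. Single genes of conjugation and quinone reduction were higher with fish oil, and a desaturase and a ribonucleotide reductase gene were lower. Ugt2b7, a glucuronosyltransferase, rose by 5.22 ± 0.15 (adjusted p = 3.42e-06), from 6.32 and 6.00 to 11.52 and 11.23, and Nqo1, a quinone reductase, by 3.26 ± 0.29. Scd, the stearoyl-CoA desaturase, was at -2.85 ± 0.26, and Rrm2 at -2.37 ± 0.31. The calls of Nqo1, Scd and Rrm2 ended whichever array of the comparison was left out, while that of Ugt2b7 was kept. In all 54 probe sets passed, 25 higher and 29 lower, and 3621 had an unadjusted p under 0.05 against 1461 by chance. The count was 5 when only these groups were fitted, 5 without either control vegetable oil array, 3 without control fish oil replicate 1 and 6 without replicate 2, and between 3 and 5 of the 24 largest changes kept their call.

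Other rises with fish oil were those of Csmd1 (2.78 ± 0.16), the export pumps Abcc2 (2.44 ± 0.14) and Abcc4 (1.5 ± 0.20), Pir (2.29 ± 0.22), Creb3l3, a transcription factor of lipid metabolism (2.05 ± 0.19), Angptl4 (1.95 ± 0.20), Gstp1, a glutathione transferase (1.75 ± 0.13), Srxn1, sulfiredoxin (1.69 ± 0.15), Cldn17 (1.58 ± 0.20) and the peroxisomal thiolase Acaa1b (1.43 ± 0.20). Other falls were those of the gelatinase Mmp9 (-2.08 ± 0.24), Paep (-1.85 ± 0.27), Mfap4 (-1.76 ± 0.21), Sectm1b (-1.59 ± 0.14), Prima1 (-1.51 ± 0.15), the histone gene Hist2h3c2 (-1.39 ± 0.15), the proteoglycan Lum (-1.30 ± 0.16), Igf1 (-1.17 ± 0.16), Fgf13 (-1.14 ± 0.14) and Nnat (-1.13 ± 0.15). Of 35 NRF2 targets and metallothioneins 8 rose (21 adjusted over the list alone, median 0.68, adjusted p = 1.87e-23; adjusted p = 0.0901 with an estimated correlation). Of 43 PPAR alpha target and fatty acid oxidation genes 4 rose (25 adjusted over the list alone, median 0.42, adjusted p = 1.84e-19; adjusted p = 0.285 with an estimated correlation), among them Vnn1, pantetheinase, at 0.94 ± 0.12. Of 49 cell cycle genes 1 fell, Rrm2 (42 adjusted over the list alone, median -1.19, adjusted p = 1.41e-33; adjusted p = 0.285 with an estimated correlation), with Aurkb at -1.56 ± 0.23, Plk1 at -1.74 ± 0.29 and Foxm1 at -1.08 ± 0.17, which did not pass over all genes.

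Matrix genes were lower by camera with fish oil (median -0.40, 1 of 36 fell and 15 adjusted over the list alone, adjusted p = 4.58e-11; adjusted p = 0.285 with an estimated correlation), as were interferon response genes (-0.35, none of 40 and 3 adjusted over the list alone, adjusted p = 5.43e-08; adjusted p = 0.505 with an estimated correlation). The complement (-0.27), macrophage (-0.34), cholesterol synthesis (-0.25) and fatty acid synthesis lists (-0.15) were lower (adjusted p = 0.000652, 0.000652, 0.00151 and 0.0133; adjusted p = 0.285, 0.593, 0.593 and 0.593 with an estimated correlation). So were thick ascending limb (-0.15), podocyte (-0.14) and endothelium lists (-0.13), with adjusted p = 0.0447, 0.0301 and 0.034, and adjusted p = 0.593, 0.593 and 0.631 with an estimated correlation. Scd was the only gene of these 7 lists that passed. The adrenal gland list was higher (0.27, adjusted p = 0.000309; adjusted p = 0.479 with an estimated correlation), with the steroidogenic gene Cyp11b1 at 0.72 ± 0.26, which did not pass. These are markers of neighbouring tissue, and whether such tissue was taken with the kidneys was not tested. The thick limb call ended without control vegetable oil replicate 1 or 2 or control fish oil replicate 1, the podocyte and endothelium calls without control vegetable oil replicate 2 or control fish oil replicate 1. The cholesterol call ended without control vegetable oil replicate 1 or control fish oil replicate 2, and the fatty acid synthesis call without the latter. The tubular injury list had a median of -0.20 and did not pass, and Havcr1 differed by -0.19 ± 0.60.

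Without choline, fish oil and vegetable oil were compared first in kidneys not labelled necrotic. The injury genes Havcr1 and Lcn2, Fgg of fibrinogen and the kininogen gene Kng2 were lower with fish oil. Havcr1 was at -4.2 ± 0.60 (adjusted p = 0.0138), Lcn2 at -2.23 ± 0.31, Fgg at -4.96 ± 0.36 and Kng2 at -3.66 ± 0.23, while Ugt2b7 rose by 4.94 ± 0.15 and Pdk4 by 1.22 ± 0.18. Slc34a1 and Umod differed by 0.10 ± 0.11 and -0.02 ± 0.13 (adjusted p = 0.825 and 0.98), and Umod changed sign under median centring (0.09) and without deficient fish oil replicate 1 (0.05) or deficient vegetable oil replicate 1 (0.01). In all 507 probe sets passed, 101 higher and 406 lower. The count was 25 when only these groups were fitted (3 higher and 22 lower), 239 without deficient vegetable oil replicate 2, 137 and 87 without deficient fish oil replicate 1 or 2, and 691 without deficient vegetable oil replicate 1. Without deficient vegetable oil replicate 2 the calls of Havcr1, Ugt2b35, Gsta3 and Nqo1 ended, and without either deficient fish oil array those of Ugt2b35, Gsta3, Nqo1, Oxgr1, Ccr2 and Fcgr2b.

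Other falls with fish oil under lack of choline were those of Olr1 (-3.99 ± 0.23), Fgb (-3.77 ± 0.34), Atf3 (-3.68 ± 0.24), Kng1 (-3.39 ± 0.24), Fga (-3.11 ± 0.17), the Fc receptor Fcgr2b (-2.79 ± 0.40), Glycam1 (-2.68 ± 0.29), the monocyte chemokine receptor Ccr2 (-2.63 ± 0.38) and the ficolin Fcnb (-2.63 ± 0.22). Rises were those of Ugt2b35 (3.32 ± 0.60), Csmd1 (2.37 ± 0.16), Pir (2.00 ± 0.22), Gsta3 (1.83 ± 0.28), Nqo1 (1.81 ± 0.29), Creb3l3 (1.63 ± 0.19), Abcc2 (1.56 ± 0.14), Tsku (1.54 ± 0.14), Abcc4 (1.52 ± 0.20), Oxgr1 (1.37 ± 0.22) and Cldn17 (1.33 ± 0.20). The Abcc4, Cldn17 and Creb3l3 calls ended without deficient fish oil replicate 2, and that of Cldn17 also without deficient vegetable oil replicate 1. The differences of the control oil comparison come from other arrays than those here. Both comparisons use the same spread, estimated over all 5 groups, so their calls are not independent. With only the groups of each fitted, 5 and 25 probe sets passed. Of the 54 calls between the control oils 43 had the same direction here, and 15 higher and 9 lower ones passed in both, with 1 passing in the opposite direction. Independent lists would give 0.09 and 0.4, numbers that do not allow for the shared spread. Across all probe sets the oil differences correlated at r = 0.245, and probe sets are not independent replicates.

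By list, cytokine genes (16 of 39 fell, 32 adjusted over the list alone, median -0.93), complement and coagulation genes (10 of 31, 17, -0.64) and p53 and cell death genes (4 of 35, 10, -0.30) were lower. Their camera adjusted p were 4.06e-27, 5.16e-16 and 1.46e-08, and these calls held with an estimated correlation (adjusted p = 0.0271, 0.0271 and 0.0372). Cxcl10, a chemokine induced by interferon, was at -1.84 ± 0.16, Csf1 at -1.65 ± 0.14, tissue factor F3 at -1.41 ± 0.13 and Ripk3 at -1.80 ± 0.24. Tubular injury (13 of 23 fell, 18 adjusted over the list alone, median -1.08) and unfolded protein genes (6 of 33, 7, -0.21) had adjusted p = 5.75e-19 and 2.22e-06, and each adjusted p = 0.071 with an estimated correlation. Timp1, a metalloproteinase inhibitor, was at -2.36 ± 0.29 and Asns, asparagine synthetase, at -1.39 ± 0.18. Macrophage (17 of 25 fell, 21 adjusted over the list alone, median -1.13), matrix (11 of 36, 15, -0.44) and immediate early genes (8 of 29, 18, -0.53) were lower (adjusted p = 4.41e-23, 1.11e-16 and 3.32e-13), each with adjusted p = 0.0949 with an estimated correlation. Cd68 was at -1.47 ± 0.20, the leukocyte antigen Ptprc at -1.38 ± 0.19, Tagln, a smooth muscle protein, at -2.32 ± 0.16 and Egr2 at -1.39 ± 0.18. PPAR alpha genes were higher (10 of 43 rose, 31 adjusted over the list alone, median 0.52, adjusted p = 5.75e-19; adjusted p = 0.0949 with an estimated correlation), with Acsl1 at 1.03 ± 0.14. NRF2 targets were higher too (7 of 35, 18, 0.34, adjusted p = 4.93e-08; adjusted p = 0.0957 with an estimated correlation), with Gstp1 at 1.13 ± 0.13.

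Interferon genes were lower in the same comparison (7 of 40 fell, 14 adjusted over the list alone, median -0.51, adjusted p = 4.22e-13; adjusted p = 0.186 with an estimated correlation), with Ifi47 at -1.37 ± 0.14 and Irf1 at -1.78 ± 0.26. Cell cycle (2 of 49 fell, median -0.63), neutrophil (2 of 15, -0.58), cholesterol (1 of 20, -0.24), lymphocyte (-0.19) and erythroid genes (-0.22) were lower (adjusted p = 3.32e-13, 1.93e-05, 0.00848, 0.00112 and 0.0394). With an estimated correlation they had adjusted p = 0.274, 0.239, 0.507, 0.18 and 0.345. Rrm2 was at -1.57 ± 0.31 and Insig1, which restrains sterol synthesis, at -1.21 ± 0.21. Collecting duct genes were higher (5 of 23 rose, median 0.23, adjusted p = 1.93e-05; adjusted p = 0.153 with an estimated correlation), with Rhcg at 0.60 ± 0.11. Proximal tubule (0.18), thick limb (0.28), distal tubule (0.26), endothelium (0.28), heat shock (0.20), mitochondrial (0.13) and choline lists (0.10) were higher by camera, with 4 rises and 3 falls among their genes. Their adjusted p were 0.00145, 0.0037, 0.00647, 0.00204, 0.0126, 2.80e-05 and 0.0361, and adjusted p = 0.457, 0.239, 0.239, 0.345, 0.261, 0.442 and 0.399 with an estimated correlation. The proximal tubule, distal tubule, heat shock, mitochondrial, choline, lymphocyte and erythroid calls ended without deficient vegetable oil replicate 2, the endothelium, cholesterol and erythroid calls without its replicate 1. The distal tubule, cholesterol and choline calls ended without deficient fish oil replicate 2, and the erythroid call without its replicate 1. The fatty acid synthesis list had a median of 0.12 and a mean of -0.13 and did not pass.

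**Figure D3:**
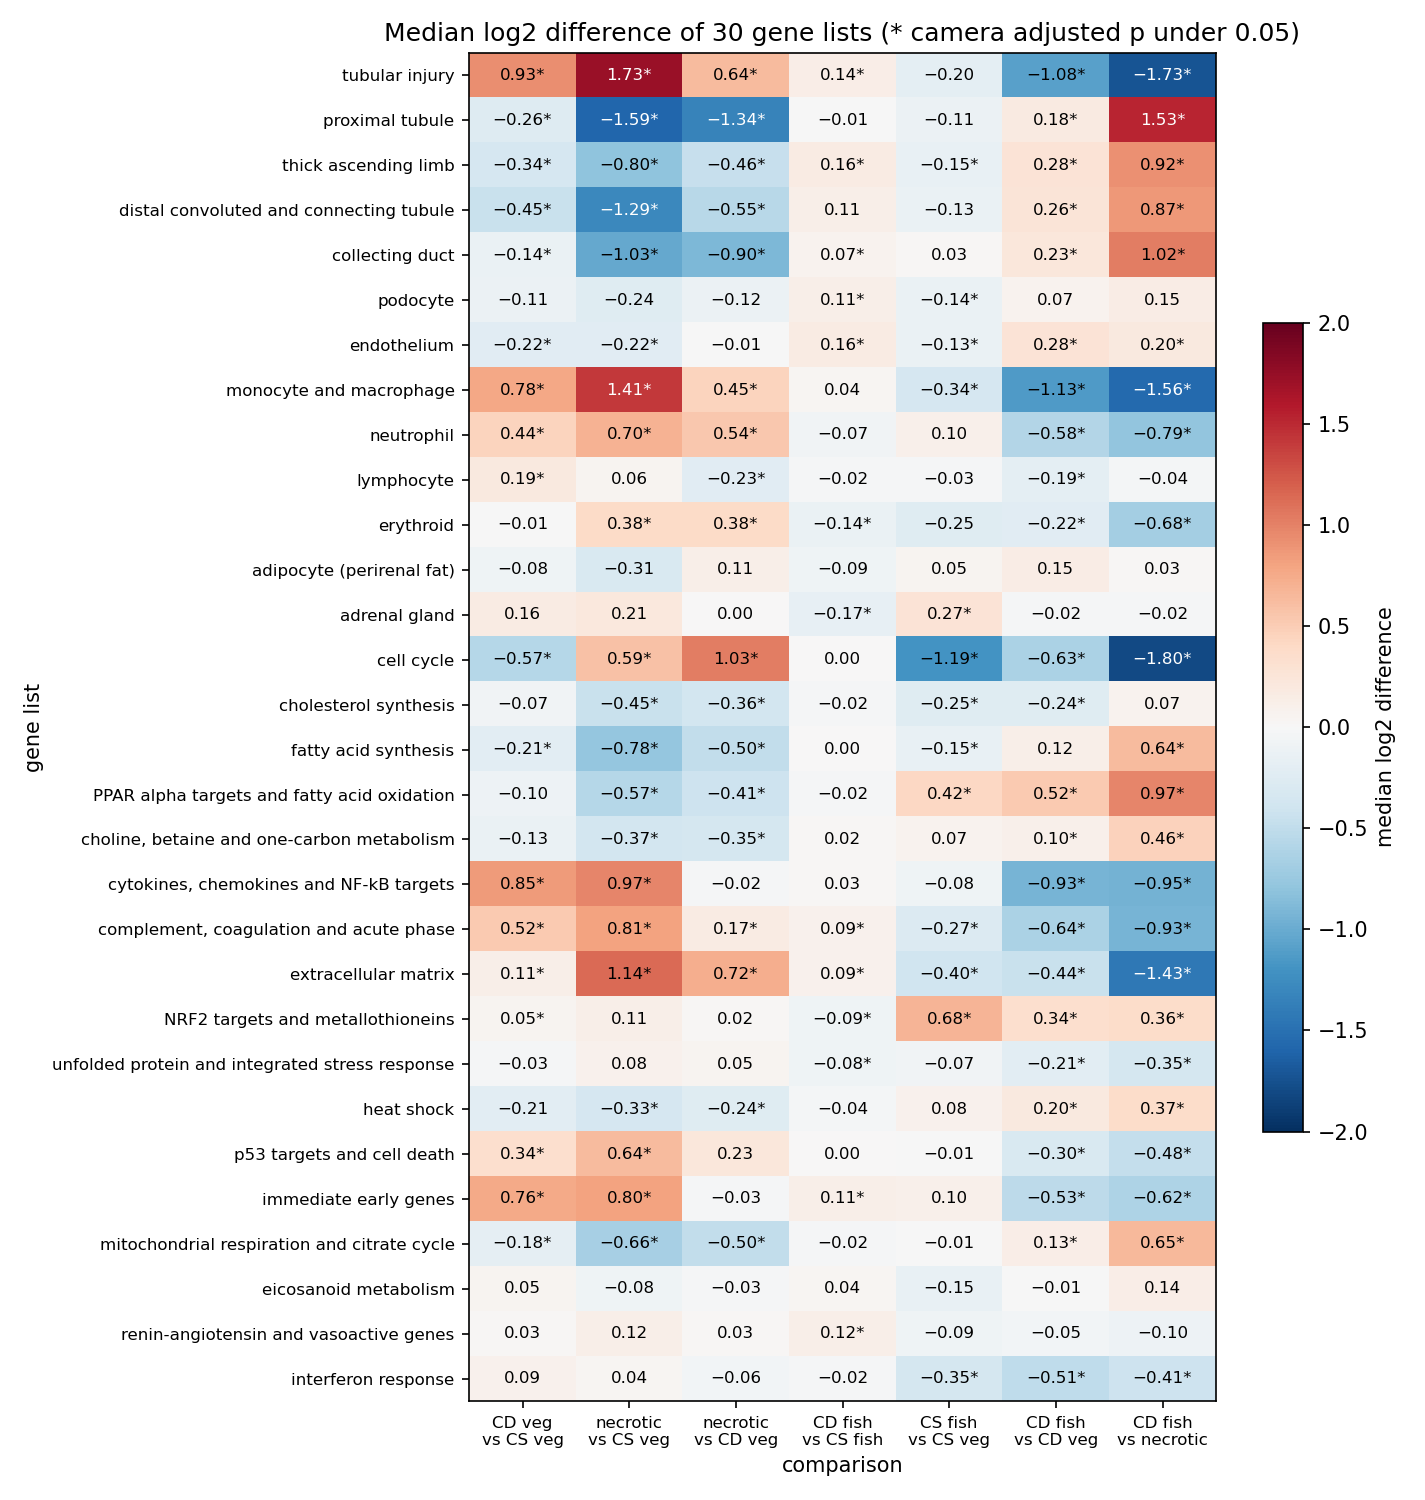
Median log2 difference of 30 gene lists (rows) in 7 comparisons (columns), written in each cell and coloured from blue (lower) to red (higher), with an asterisk where camera gave an adjusted p under 0.05. Tubular injury has 0.93 and 1.73 in the deficient and necrotic vegetable oil kidneys against control and 0.14 with fish oil.

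Finally, deficient fish oil kidneys were compared with the necrotic kidneys. In this comparison and the previous one, oil and the sorting by label cannot be told apart. The tubule genes Slc34a1, Umod, Egf and Klk1 were higher and the injury genes Havcr1 and Lcn2 lower with fish oil. Slc34a1 rose by 3.36 ± 0.11, Umod by 3.09 ± 0.13, Egf by 4.81 ± 0.17 and Klk1 by 4.80 ± 0.19, while Havcr1 was at -5.13 ± 0.60, Lcn2 at -3.34 ± 0.31, Clu at -2.52 ± 0.30 and Fgg at -6.04 ± 0.36. In all 5763 probe sets passed, 2701 higher and 3062 lower. After median centring 3466 were higher and 2147 lower, and without deficient fish oil replicate 1 or 2 the count was 3380 and 3324. Other rises were those of Ugt2b35 (5.83 ± 0.60), Ugt2b7 (5.09 ± 0.15), Dnase1 (4.79 ± 0.15), Acsm3 (4.43 ± 0.14), Slco1a6 (4.42 ± 0.31), Acmsd (4.35 ± 0.25), Slc7a12 (4.30 ± 0.29) and Klk1b3 (4.19 ± 0.10). Other falls were those of Serpina3n (-5.30 ± 0.68), C3 (-4.53 ± 0.40), Cxcl2 (-4.35 ± 0.25), A2m (-4.31 ± 0.26), Fgb (-4.19 ± 0.34), Olr1 (-4.02 ± 0.23), Gpnmb (-3.72 ± 0.22), Niban1 (-3.61 ± 0.20) and the lactate transporter Slc16a3 (-3.57 ± 0.26).

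Of the lists in this comparison, proximal tubule (36 of 42 rose and 1 fell, median 1.53), PPAR alpha (34 of 43 rose and 3 fell, 0.97), mitochondrial (33 of 48 rose, 0.65) and choline genes (19 of 41 rose and 4 fell, 0.46) were higher. Camera gave adjusted p = 1e-20, 1.33e-14, 3.52e-15 and 0.000153, and the adjusted p was 0.129, 0.152, 0.185 and 0.183 with an estimated correlation. Gnmt, glycine N-methyltransferase, was at 2.70 ± 0.21 and Pdha1, of pyruvate dehydrogenase, at 1.04 ± 0.12. Thick limb (7 of 11 rose and 1 fell, 0.92), distal tubule (7 of 13, 0.87) and collecting duct genes (16 of 23 rose and 1 fell, 1.02) were higher, with adjusted p = 0.157, 0.0884 and 0.0884 with an estimated correlation, as were NRF2 (15 of 35 rose and 3 fell, 0.36), heat shock (8 of 18 rose and 1 fell, 0.37), fatty acid synthesis (9 of 19 rose and 1 fell, 0.64) and endothelium genes (4 of 19, 0.20), with adjusted p = 0.19, 0.183, 0.328 and 0.564. Osgin1 was at 2.54 ± 0.19 and Me1, malic enzyme, at 1.37 ± 0.18. Cell cycle (43 of 49 fell, median -1.80), macrophage (21 of 25, -1.56), matrix (32 of 36 fell and 1 rose, -1.43) and injury genes (20 of 23, -1.73) were lower. Their camera adjusted p were 1.70e-18, 2.28e-14, 5.63e-18 and 3.01e-13, and adjusted p = 0.186, 0.157, 0.0884 and 0.0884 with an estimated correlation. Rrm2 was at -3.34 ± 0.31, Mrc1 at -3.39 ± 0.22 and Tagln at -2.66 ± 0.16.

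Cytokine (25 of 39 fell, -0.95), complement (20 of 31, -0.93), p53 (18 of 35 fell and 1 rose, -0.48) and immediate early genes (15 of 29, -0.62) were also lower against the necrotic kidneys, with adjusted p = 0.0884, 0.0884, 0.0884 and 0.183 with an estimated correlation. Neutrophil (7 of 15, -0.79), erythroid (8 of 12, -0.68), interferon (12 of 40 fell and 1 rose, -0.41) and unfolded protein genes (10 of 33 fell and 4 rose, -0.35) were lower too, with adjusted p = 0.209, 0.157, 0.417 and 0.185 with an estimated correlation. Ccl3 was at -3.26 ± 0.13, Casp4, an inflammatory caspase, at -1.75 ± 0.21, Hba-a3, an alpha globin, at -1.04 ± 0.24 and Slc7a5, an amino acid carrier, at -2.71 ± 0.17. The endothelium call ended without deficient fish oil replicate 2 or necrotic replicate 1, and the unfolded protein call without necrotic replicate 2. The eicosanoid list had 7 genes higher and 7 lower of 35 and did not pass, with a median of 0.14, and the renin-angiotensin list had 6 higher and 6 lower of 26.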

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

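The tests of whether the choline effect differed between the oils were planned; all tests of explanations in this part were chosen only after the result was seen. With necrotic kidneys as the deficient vegetable oil arm, oil and the sorting by label cannot be told apart. In that test 2548 probe sets differed in their choline effect between vegetable and fish oil. The highest were Havcr1 (4.94), Serpina3n (4.78), Hmox1 (4.76), Fgg (4.71), Gpnmb (4.24), Cxcl2 (4.17), A2m (4.03), Trh (3.99), Olr1 (3.86), Lbp (3.75), Mmp7 (3.75) and C3 (3.74). The lowest were Cacng5 (-5.90), Calb1 (-5.31), Egf (-5.05), Folh1 (-4.87), Rgn (-4.81), Klk1 (-4.75), Acsm3 (-4.62), Acmsd (-4.58), Dnase1 (-4.5), Spp2 (-4.39), Hnmt (-4.38) and Slco1a6 (-4.38). Serpina3n lost its call without necrotic replicate 1, either control vegetable oil array or deficient fish oil replicate 2.

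With deficient vegetable oil kidneys not labelled necrotic, 30 probe sets differed in the same test. They include Kng2 (3.85), Olr1 (3.82), Atf3 (3.74), Igfbp1 (2.96), Kng1 (2.95), Fga (2.95), Socs3 (2.51), Myc (2.24), Angptl4 (2.18), Tnfrsf12a (2.16), Inhba (2.13), Mthfd2 (2.07), Prima1 (-1.69) and Or13a19b (-1.29). None of these 14 kept its call without any 1 of the 4 control arrays.

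Replicate 2 of the deficient vegetable oil kidneys lay between replicate 1 and the necrotic arrays. Suppose necrotic tissue RNA was mixed into that pool and the rest of the pool matched replicate 1. Probe sets high and low in necrotic kidneys should then give 1 mixed fraction. The median fraction was 13.2% for 44 high and 46% for 228 low probe sets, a difference of -32.8 points (-38.7 to -25.2). Intervals here are bootstraps over probe sets, treated as independent. The difference argues against such a mixture. It does not exclude a mixture in which the rest of the pool, from other animals, differed from replicate 1. Between tubular injury genes (41.6%, 16 genes) and macrophage genes (44.8%, 18 genes) the difference was -3.2 points (-43.2 to 32.1), too wide to decide. A pool of animals at an earlier or milder stage of injury stays open as a candidate explanation and was not tested.

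Proximal tubule markers were lower in necrotic kidneys. Intervals in brackets here are bootstraps over genes, treated as independent. Dilution of all resident cells by entering cells would lower podocyte and endothelium markers alike, but these 33 markers (median -0.22) stood 1.36 above the tubule markers (0.96 to 1.81). A lower tubule share would raise all other cell types alike, but macrophage markers stood 1.63 above podocyte and endothelium markers (1.13 to 2.08). Both tests take a cause as acting alone. Neither excludes a lower tubule share together with entering macrophages, a combination that was not tested. Loss of tubule cells as 1 uniform type would lower 41 bright markers equally if probe sets respond alike and other cells lack these genes. That condition was not tested. The changes of these markers had an SD of 1.03 (0.80 to 1.21) against a standard error of 0.14, from -4.23 for Miox to 0.24 for Slc2a2. The falls were unequal, which does not by itself exclude a uniform loss. Unequal loss of tubule segments, entering macrophages and lower expression per cell may all contribute, and these arrays cannot separate them.

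The cell cycle list was lower by camera with fish oil when choline was given (median -1.19, 1 of 49 genes passed, adjusted p = 0.285 with an estimated correlation). A single array does not set this, as the list median stayed between -1.33 and -1.02 when 1 array was left out. A permutation of genes of like brightness argues against a shift of them all: of 10000 random lists the lowest median was -0.19 (permutation p = 1e-04, the smallest they can give, which treats genes as independent). Over the 4 fish oil and 4 vegetable oil arrays not labelled necrotic, the mean level differed by -0.90 (exact permutation p = 0.0286, the smallest that 70 splits can give), which decides nothing, since the list was picked on these arrays. Between the deficient oils, on other arrays, 2 of 49 genes passed (list median -0.63, adjusted p = 0.274 with an estimated correlation), so whether the oil acts at both choline supplies stays open.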

How the results depend on the processing

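Except for 1 added later, these alternatives were fixed before the values were seen. Median centring, quantile normalization again and cyclic loess kept all 9 counts within 1.5 times. Without probe sets below the 25th percentile of the mean, 115 (control fish against control vegetable oil) and 61 (interaction, not necrotic) passed. Below the 50th percentile removed, 542 passed for deficient against control vegetable oil, 118 for the control oils and 87 for that interaction; with a trend and robust prior these were 540, 124 and 67. With only the groups of a contrast, 82 (deficient against control vegetable oil), 654 (necrotic against deficient), 5 (control oils), 25 (deficient fish against deficient vegetable oil) and 14 (interaction, not necrotic) passed. Array weights gave 1674 for necrotic against deficient, 162 for the control oils and 46 for the interaction. With probe sets of 1 symbol only, added after the data were seen, 577 (deficient against control vegetable oil), 130 (control oils), 761 (deficient oils) and 112 (interaction, not necrotic) passed. Samples of different groups share only a number; with a replicate block 5779, 255, 2678, 0, 41, 5503, 427, 2336 and 11 passed in the 9 contrasts. Deviations of replicate 1 correlated between groups at -0.173 to 0.136 across probe sets, which are not independent replicates. With 1 array left out, the counts ranged from 3003 to 4638 (necrotic against control), 32 to 714 (deficient against control vegetable oil), 1040 to 3125 (necrotic against deficient), 0 to 2 (fish oil with and without choline), 3 to 6 (control oils), 3324 to 4254 (deficient fish oil against necrotic), 87 to 691 (deficient oils), 955 to 1847 (interaction, necrotic) and 0 to 90 (interaction, not necrotic). The gene signs that turned belong to differences that did not pass. Umod between the deficient oils was 0.09 under median centring and -0.09 to 0.05 with 1 array left out, with 0.01 without deficient vegetable oil replicate 1. Pdk4 in the interaction, not necrotic, was -0.32 to 0.14 and Clu between the control oils -0.09 to 0.14. For lack of choline under fish oil the ranges were S100a6 -0.03 to 0.91, Elf5 0.00 to 0.58, Clu -0.11 to 0.25 (with -0.04 without control replicate 1), Slc34a1 -0.02 to 0.02, Umod -0.05 to 0.20 and Nr4a2 -0.05 to 0.82. In that contrast the list direction turned for tubular injury (adjusted p 3.72e-09 to 0.974), immediate early genes (7.72e-05 to 0.974) and erythroid genes (8.2e-09 to 0.688), and in the interaction, not necrotic, for interferon genes (5.5e-06 to 0.93). Of 173 list calls 4 held with an estimated correlation, while 105 held and 68 ended with fry. A call that ended with an estimated correlation need not mean correlated genes. The p53 list, necrotic against control, had a correlation of 0.022, with camera adjusted p = 0.0988 against 9.58e-06 at the preset 0.01. Fry values are given above for some lists only. Of 862 named gene values 832 were the same with array weights and 714 with only the groups of a contrast. The cause was not tested.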

Other observations

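All tests of explanations in this part were chosen only after the result was seen. A small set of genes was higher in the deficient vegetable oil kidneys than in both the control and the necrotic kidneys. Csrp3, a muscle LIM protein, stood at 10.48 and 8.29 in these kidneys, 6.07 and 6.17 in the controls and 6.96 and 6.50 in the necrotic kidneys. Fcnb, a ficolin, was higher than control by 2.17 and lower in necrotic than in deficient kidneys (-2.01 ± 0.22), Cxcl10 by 1.30 and -1.71 ± 0.16, and Slc10a2, the bile acid transporter, by 1.41 and -1.31 ± 0.12. Ch25h, which makes an oxysterol, Guca2a, a guanylin, and Ccl4 had -1.32 ± 0.21, -1.23 ± 0.31 and -1.12 ± 0.14 in necrotic against deficient kidneys. Kng2, Kng1 and Atf3 were lower in necrotic than in deficient kidneys (-2.34 ± 0.23, -1.26 ± 0.24 and -1.14 ± 0.24) and still above control by 1.72, 2.02 and 2.82.

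There were 25 such probe sets, 21 with 1 symbol. Independent lists would give 13.3, a number that does not allow for shared arrays. Both comparisons share the deficient arrays, so high chance values there would produce such a set. When the set was chosen with 1 deficient array left out, that array lay above all control and necrotic arrays in 18 of 21 and 27 of 30 probe sets. The shares are 85.7% and 90%. They decide nothing about chance, since the probe sets were chosen for low values on the arrays compared, which raises the share by an unknown amount. These genes may mark a stage of injury that the necrotic kidneys had passed, or animals that responded differently; all kidneys were taken at 1 time, and neither was tested.

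Ugt2b7, a glucuronosyltransferase, was higher with fish oil at both choline supplies. It stood at 10.63 and 10.74 in deficient and 11.52 and 11.23 in control fish oil kidneys, and between 5.56 and 6.32 on the 6 vegetable oil arrays. The mean level of the NRF2 target list was higher with fish oil by 0.63 and that of the PPAR alpha list by 0.51, over 4 fish oil and 4 vegetable oil arrays not labelled necrotic. Each had exact permutation p = 0.0286, the smallest that 70 splits can give, which decides nothing, since the lists were picked on these arrays. With an estimated correlation neither list passed between the control oils (adjusted p = 0.0901 and 0.285) or the deficient oils (0.0957 and 0.0949). Levels were 11.44 to 11.62 on fish oil and 10.73 to 11.13 on vegetable oil arrays for NRF2 targets. A candidate explanation is that fatty acids of fish oil act through these regulators; regulator activity was not measured.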
